A study of Mus musculus with 12 samples.

How the data were processed

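Total RNA of cultured astrocytes from cortex and hippocampus of adult mice was extracted with TRIzol and made into libraries by standard Illumina protocols, per the labels. Tissue had been dissociated with trypsin and papain, and no sorting of cells is described. The labels give mm10 as the genome build. The aligner, the counting tool, the annotation release and the treatment of reads that match several genes are not given in the sources used here. The authors deposited a table of FPKM (fragments scaled to gene length and library size) for 54532 genes, with 1 column per library and the length of each gene. Each FPKM times its gene length was a whole multiple of 1 step per library (100% of values within 0.1 of a read), which gave back the reads per gene, 16418852 to 18705309 per library. That total was 0.886 to 1.10 times the library size behind the deposited values. The median-of-ratios factor of the values was 1.01 in every library, so the deposited FPKM were already on that scale, by a method the labels do not give.

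Samples were grouped by the labels, with 2 libraries in each of 6 groups. The genotype label is identical for the Ogt cKO and its control, and the groups were told apart by the sample descriptions. The Aβ exposure is given as 72 hours in the protocol and as 73 hours in the characteristics of 1 sample, and the ages of the mice differ between the experiments (4, 6 and 2 months), not within them. Tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined. Genes with at least 1 FPKM in at least 2 of the 12 libraries were kept (14014, of which 12344 protein coding). Expression was tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 libraries sharing 1 estimate of the spread (6 residual degrees of freedom, 2.92 prior ones), an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over genes at 0.05. Because of the added 1, a fitted log2 change is smaller than the ratio of mean FPKM where either mean is low. Differences between the effects of 2 experiments were contrasts of the same fit. Overlaps were set against the product of the 2 counts over all genes tested, with a one-sided hypergeometric test. Overlaps of all 3 experiments were set against the genes shared by AD and Aβ times the share of all genes called in the cKO, without a test, and this was chosen after the values were seen.

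The gene lists, 33 in number, covered the O-GlcNAc pathway, reactive astrocyte genes, inflammatory and antigen presentation pathways, metabolism, stress, cell cycle, matrix, cell death and markers of brain cell types. The sex-linked list was not tested and the list of blood cells had under 3 measured genes, which left 31 for camera with a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. The same lists were also run with an estimated correlation and with fry. A list's counts of members that rose or fell come from the test over all genes, and the counts adjusted over the list alone stand beside them. The genes named are Ogt and Oga (Mgea5), the 8 with the largest rise and the 8 with the largest fall per comparison among those past the threshold, with a mean of at least 5 FPKM in the higher group, groups that did not overlap and no predicted gene name, up to 4 members per list by p, and across comparisons the 8 called in the same direction in most of them and the 4 per pair with the largest difference. Levels of Gfap, Lyz2, Col1a1, Snap25 and Acta2, and of C1qa and Apoe where given for all groups, were chosen after the values were seen.

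The test was tried on data simulated with the depth and spread of each experiment. It recovered 92%, 56% and 86% of planted 2-fold changes for cKO, AD and Aβ and 100%, 97% and 97% of 4-fold ones. False calls made up 7.69%, 9.47% and 2.66% of the calls, so the adjusted p of the cKO and AD calls may be somewhat too small. These shares rest on 16, 16 and 5 false calls in 1 simulated data set per comparison. Each data set gave all genes and all 12 libraries the same spread, unlike the real data. With no gene changed and each experiment at its own spread, 0, 1 and 0 of 13202 genes were called. The alternatives planned were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, robust empirical Bayes, a minimum log2 change of 1, the 4 libraries of a comparison alone, and leaving out each library. After seeing the data 4 were added, which are voom on the recovered reads, rescaling to the total of these reads, removal of a smooth trend on GC content and gene length per library (natural splines with 5 degrees of freedom, GC content from the transcripts of each gene), and a crossed pairing of replicates. Plots were made with matplotlib 3.10.9 in Python 3.11.15.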

Results

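RNA sequencing was done on cultures of astrocytes, the main support cells of the brain, taken from cortex and hippocampus of adult C57BL/6 mice. The 12 libraries formed 6 groups of 2 in 3 experiments, each with its own control group. The cKO experiment compared astrocytes of 4-month-old mice with a conditional knockout (cKO) of Ogt with their controls. Ogt is the X-linked enzyme that attaches the sugar O-GlcNAc to proteins, and the Glast-CreERT2 driver removes floxed sequence in astrocytes after tamoxifen. No tamoxifen treatment is described in the labels, and the genotype label is the same for the Ogt cKO and its control. The AD experiment compared astrocytes of an amyloid mouse model of Alzheimer's disease (5X APP) with controls, given as 6 months old in the sample labels and 5 months old in the series description. The Aβ experiment compared control astrocytes of 2-month-old mice with astrocytes kept for 72 hours in 20 µM amyloid-beta 1-42 (Aβ), the peptide that forms plaques. The labels do not say whether the 2 replicates of a group came from separate animals or cultures, so every p-value measures the spread between these samples only, which may be technical.

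Each library held 16418852 to 18705309 reads assigned to genes, and 14014 of the 54532 genes in the table were tested. At this depth 3 reads on a gene of 1 kilobase correspond to 0.145 to 0.191 FPKM, a limit that covers counting error only. All 6 groups held transcripts of several cell types. The lipid carrier gene Apoe ranged from 445 FPKM in the Ogt cKO to 4498 in its control. The astrocyte filament gene Gfap ranged from 51.7 in the Ogt cKO to 282 in its control. The smooth muscle actin Acta2 reached 382 FPKM or more in every group, the collagen Col1a1 195 or more, and the microglia and macrophage genes C1qa and Lyz2 183 or more and 740 or more, while the neuronal Snap25 was at 0 to 0.0375 FPKM in the 12 libraries.

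The first principal component held 38.7% of the variance and set the AD model and Aβ-treated libraries apart from the others. The second held 36.2% and separated the cKO control libraries from the Ogt cKO, Aβ control and Aβ-treated libraries. The Ogt cKO libraries lay beside the Aβ control libraries, and the AD control libraries lay apart from one another. Replicates correlated at r = 0.988 in the cKO control, 0.991 in the Ogt cKO, 0.987 in the Aβ control and 0.985 in the Aβ-treated group, but at 0.948 in the AD control and 0.944 in the AD model, across genes, which are not independent replicates. AD control replicate 2 correlated more with cKO control replicate 1 (r = 0.963) than with its own replicate, and AD model replicate 1 more with Aβ-treated replicate 1 (r = 0.974).

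**Figure D1:**
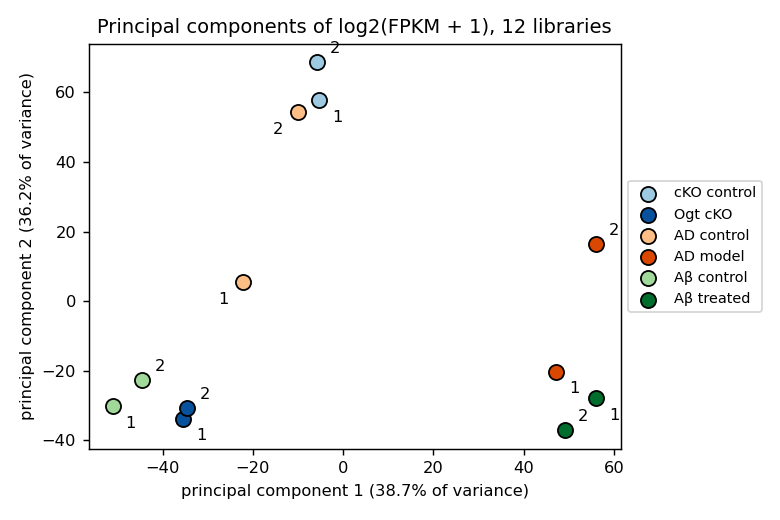
Principal components of log2(FPKM + 1) over 14014 genes, with component 1 (38.7% of variance) on the horizontal axis and component 2 (36.2%) on the vertical axis, both in score units; each point is 1 of the 12 libraries, coloured by group and numbered by replicate. The AD model and Aβ-treated libraries lie at 47.3 or higher on component 1 and all other libraries below 0, and the AD control replicates lie at 5.41 and 54.3 on component 2.

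The cKO comparison asks what loss of Ogt does to adult astrocytes. Ogt (ENSMUSG00000034160, chrX:101640060-101684351 in mm10) was at 22.7 ± 2.74 FPKM in the control and 11.5 ± 0.698 in the Ogt cKO (SD, n = 2), a log2 change of -0.92 ± 0.30 (SE, adjusted p = 0.038). Oga, listed under its older symbol Mgea5 (ENSMUSG00000025220, chr19:45750261-45783520), encodes the enzyme that removes O-GlcNAc and fell from 43.2 ± 0.243 to 16.2 ± 0.544 FPKM (log2 change -1.36 ± 0.38, adjusted p = 0.020). Both values cover the whole gene and do not resolve the floxed exons. Ogt in wild-type libraries of the other experiments went as low as in the Ogt cKO, at 7.85 FPKM and 10.4 in the Aβ control libraries and at 10.0 and 22.7 in the AD control libraries. The fall of Ogt lost its call without any single library of the comparison, with adjusted p = 0.085 without cKO control replicate 1, 0.17 without cKO control replicate 2, 0.15 without Ogt cKO replicate 1 and 0.11 without Ogt cKO replicate 2, as well as with no filter on low values (0.088). The log2 change of Ogt stayed between -1.03 and -0.80 without 1 library, and was -0.74 (adjusted p = 0.062) with the trend on GC content and length removed. Ogt kept its call with the 4 cKO libraries alone (adjusted p = 0.00325), with the replicate number as a block (0.023) and with rescaling to the total of reads (0.026). Mgea5 lost its call too without any single library (log2 change -1.39 to -1.33, adjusted p = 0.077 to 0.090) and with no filter (0.053).

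**Figure D2:**
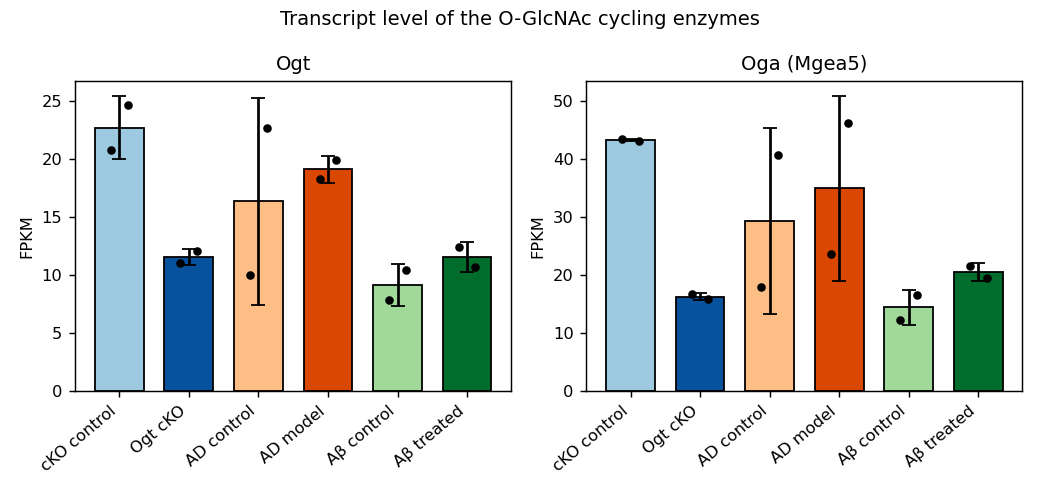
Level of Ogt (left) and of Oga, listed as Mgea5 (right), in FPKM on axes that start at 0; bars are group means, error bars the SD of 2 libraries and dots the libraries. Ogt averages 22.7 FPKM in the cKO control, 11.5 in the Ogt cKO and 9.12 in the Aβ control, and the AD control libraries lie at 10.0 and 22.7.

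Crct1 and Ccl2 were among the 8 genes with the largest rise in the Ogt cKO, and Selenop and Apod among the 8 with the largest fall. Crct1, a cornified envelope gene (chr3:93014205-93015687), went from 16.9 ± 14.8 to 1032 ± 31.5 FPKM (log2 change 6.15 ± 0.84, adjusted p = 0.0018). Ccl2, which attracts monocytes (chr11:82035571-82037453), went from 4.60 ± 1.87 to 351 ± 18.9 FPKM (6.01 ± 0.29, adjusted p = 2.9e-05). Its neighbour Ccl7 went from 2.21 to 191 FPKM, the surface glycoprotein gene Msln (mesothelin) from 0.271 to 80.3, the growth factor binding protein gene Igfbp4 from 9.71 to 624, the matrix protease gene Mmp3 from 0.433 to 83.6, the scavenger receptor gene Marco from 0.309 to 71.5 and Lce1h, another cornified envelope gene, from 0.0376 to 70.6. Selenop, which carries selenium (chr15:3268547-3280508), fell from 544 ± 92.2 to 12.9 ± 1.76 FPKM (-5.28 ± 0.35, adjusted p = 1.3e-04). The apolipoprotein gene Apod fell from 241 to 8.40 FPKM, the lipoprotein lipase gene Lpl from 36.5 to 0.677, the collagen gene Col8a2 from 19.2 to 0.189, the glutamine transporter gene Slc38a3 from 42.6 to 2.22, the iron exporter gene Slc40a1 from 17.7 to 0.477, the matrix gene Matn2 from 40.1 to 2.28 and Fam180a from 37.7 to 0.996. Among these 16 genes the adjusted p ranged up to 0.0038.

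NF-kB genes, the targets and parts of a central inflammatory signalling pathway, rose in the Ogt cKO. Of 34 measured, 29 rose and 1 fell (32 and 1 adjusted over the list alone), with a median log2 change of 2.48 (camera adjusted p = 1.7e-15, and adjusted p = 0.58 with an estimated correlation). The neutrophil chemokine gene Cxcl2 went from 0.236 ± 0.102 to 46.3 ± 1.74 FPKM and Cxcl1 from 0.263 to 18.4. Of 11 genes of the A2 list, reported for astrocytes after ischaemia, 8 rose and 0 fell, the same counts as adjusted over the list alone (median 1.82, adjusted p = 7.3e-04). Ptx3 went from 6.20 to 92.2 FPKM, the prostaglandin synthase gene Ptgs2, which the NF-kB list also holds, from 2.66 to 95.7, and Clcf1 from 3.01 to 18.0. Of 32 cell cycle genes 29 rose and 0 fell, also adjusted over the list alone (median 1.84, adjusted p = 8.7e-13). The ribonucleotide reductase gene Rrm2 went from 4.97 ± 2.72 to 47.2 ± 0.831 FPKM and the kinase gene Cdk1 from 2.23 to 16.0. Of 36 genes of oxidative phosphorylation 18 rose and 0 fell (19 and 0 adjusted over the list alone; median 0.37, adjusted p = 6.9e-05), among them Cycs (cytochrome c), from 15.9 to 37.4 FPKM. That list lost its call with quantile normalization (median 0.07, adjusted p = 0.34), and its median was 0.15 with the trend on GC content and length removed. Of 23 genes of cholesterol synthesis 12 rose and 0 fell, also adjusted over the list alone (median 0.55, adjusted p = 0.012), among them Cyp51, from 15.0 to 31.4 FPKM. With an estimated correlation the adjusted p was 0.74 for the A2, cell cycle, oxidative phosphorylation and cholesterol lists. The markers of microglia, which also use these inflammatory genes, fell in the same libraries (median -0.92).

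Markers of mature astrocytes fell in the Ogt cKO, with 17 of 30 lower and 3 higher (17 and 4 adjusted over the list alone; median -1.64, adjusted p = 1.1e-04). The glutamate transporter gene Slc1a3, which encodes GLAST, fell from 23.5 ± 1.53 to 2.52 ± 0.0922 FPKM (log2 change -2.80 ± 0.24, adjusted p = 4.5e-04), Aldoc from 54.4 to 5.25 and Atp1b2 from 131 to 12.2. Of 20 genes for amyloid processing, uptake and clearance 9 fell and 1 rose, also adjusted over the list alone (median -0.59, adjusted p = 0.013). Apoe fell from 4498 ± 312 to 445 ± 33.2 FPKM and Abca1, which loads lipid onto it, from 34.3 to 5.24. Clu fell from 162 to 24.6 and Cst3 from 1754 to 438, and both are also on the astrocyte list. Microglia markers fell in the same libraries, so the cells that lost these transcripts cannot be told. Markers of other cell types moved both ways. Of 19 microglia markers 10 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.92, adjusted p = 2.1e-04). C1qa was at 1058 and 183 FPKM and C1qc at 596 and 80.2. Of 14 oligodendrocyte markers 7 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.81, adjusted p = 0.0033). Cnp was at 86.6 and 13.3 FPKM. Of 16 endothelial markers 10 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.83, adjusted p = 0.0033). Esam was at 4.49 and 78.8 FPKM. With an estimated correlation the adjusted p was 0.74 for all 5 of these lists. Of 10 pericyte and smooth muscle markers 5 rose and 1 fell, also adjusted over the list alone, among them Acta2, from 645 to 3594 FPKM, and Cnn1, from 20.5 to 282. That list was not called (median 1.11, adjusted p = 0.21), with a median of 0.54 without cKO control replicate 2. The interferon-stimulated genes (6 of 31 rose and 1 fell, median 0.25, adjusted p = 0.33), MHC class I (median -0.20, adjusted p = 0.64) and A1 genes (median -0.06, adjusted p = 0.79) were not called. Without cKO control replicate 1 the interferon list (median 0.45, adjusted p = 0.017) and the pericyte and smooth muscle list (1.69, adjusted p = 0.023) were called.

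In total 3165 genes were higher and 2769 lower in the Ogt cKO, which is 42.3% of those tested, and 2310 of these differed by at least 1 on the log2 scale. The count was 3213 without cKO control replicate 1, 1857 without cKO control replicate 2, 2216 without Ogt cKO replicate 1 and 2714 without Ogt cKO replicate 2. With the values rescaled to the total of reads per library, the median log2 change of all genes shifted by -0.19 and the share of calls that were higher went from 53.3% to 35.5%.

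The AD comparison asks how astrocytes of the amyloid model differ from those of wild-type mice. Cxcl1 and Irf7 were among the 8 genes with the largest rise, and Gpr37l1 and C1ql1 among the 8 with the largest fall. Cxcl1, which attracts neutrophils (ENSMUSG00000029380, chr5:90891241-90893115), went from 0.644 ± 0.317 FPKM in the control to 128 ± 17.5 in the AD model (SD, n = 2; log2 change 6.30 ± 0.23, adjusted p = 2.7e-06). Irf7, a transcription factor of the interferon response (chr7:141262706-141266481), went from 1.34 ± 0.776 to 127 ± 21.4 FPKM (5.81 ± 0.31, adjusted p = 8.3e-06). The chemokine gene Cxcl5 went from 0.0273 to 68.7 FPKM, the formyl peptide receptor gene Fpr1 from 0.115 to 97.8 ± 54.8, the antiviral gene Rsad2 from 0.195 to 110 ± 91.8, H2-Q6 of MHC class I from 0.317 to 67.4 ± 26.4, Acod1, which makes itaconate, from 0.155 to 66.7 ± 56.9, and the interleukin gene Il1a from 0.277 to 77.0 ± 73.8. Gpr37l1, a receptor gene of astrocytes (chr1:135160234-135167681), fell from 135 ± 10.9 to 12.3 ± 0.110 FPKM (-3.35 ± 0.22, adjusted p = 2.4e-05), and C1ql1, a secreted protein gene, from 19.6 ± 7.18 to 1.13 ± 0.137. The elastin gene Eln, at 51.6 ± 62.9 and 0.355 ± 0.387 FPKM, the muscle filament gene Des, at 106 ± 84.1 and 9.46 ± 5.20, and the matrix gene Nov, at 32.9 ± 24.8 and 2.57 ± 2.11, fell as well, with large differences between control replicates. With the 4 AD libraries alone Eln (adjusted p = 0.18), Des (0.12), Nov (0.13) and the rise of Il1a (0.057) lost their calls. The smooth muscle actin gene Actg2 (276 ± 280 FPKM in the control, log2 change -3.73), Mgp, which limits calcification (224 ± 185 and 22.2 ± 24.7, log2 change -3.59) and the neuropeptide gene Npvf (18.4 ± 21.9 and 0.206) passed the test with all libraries. Actg2 and Mgp did not pass without AD control replicate 1 (log2 change -2.44 and -2.63, adjusted p = 0.14 and 0.092) or AD model replicate 2 (-2.25 and -2.17, adjusted p = 0.13 and 0.057), and Npvf did not without AD model replicate 1 (0.063) or 2 (0.061). With no filter on low values the adjusted p of Actg2, Mgp and Npvf was 0.083, 0.055 and 0.059, and with the 4 libraries alone 0.27, 0.23 and 0.23. Ogt was at 16.3 ± 8.94 and 19.1 ± 1.15 FPKM (0.32 ± 0.30, adjusted p = 0.55) and Mgea5 at 29.3 ± 16.1 and 34.9 ± 15.9 (0.28 ± 0.38, adjusted p = 0.68), so neither passed the test. Without AD control replicate 2 the Ogt difference was 0.87 and did pass (adjusted p = 0.021).

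Interferon-stimulated genes rose in the AD model, 30 of 31 with 0 lower, also adjusted over the list alone (median log2 change 4.15, adjusted p = 7.8e-38). Ifi44 went from 0.387 ± 0.347 to 27.3 ± 2.17 FPKM, Gbp3 from 2.28 to 70.2 and the nucleic acid sensor gene Zbp1 from 0.721 to 41.5. All 16 genes of MHC class I presentation rose, also adjusted over the list alone (median 2.69, adjusted p = 2.6e-22). H2-Q4 was at 4.50 ± 1.71 and 101 ± 0.570 FPKM and the regulator gene Nlrc5 at 0.209 and 5.73. Of 34 NF-kB genes 28 rose and 0 fell (29 and 0 adjusted over the list alone; median 2.44, adjusted p = 1.9e-24). Cxcl2 was at 0.277 ± 0.0606 and 29.2 ± 0.635 FPKM and Ccl2 at 10.7 and 480. Of 11 A1 genes, reported for astrocytes after a bacterial endotoxin, 7 rose and 1 fell (9 and 1 adjusted over the list alone; median 2.10, adjusted p = 3.8e-07), and 3 of that list (H2-T23, H2-D1 and Psmb8) are also in the MHC class I list. Of 13 markers of disease-associated microglia 6 rose and 0 fell, also adjusted over the list alone (median 1.33, adjusted p = 3.1e-04). Clec7a was at 4.38 and 82.4 FPKM. These 5 lists stayed called with an estimated correlation, each at adjusted p = 0.046. In the same libraries 13 of 19 microglia markers rose and 0 fell (14 and 2 adjusted over the list alone; median 1.28, adjusted p = 1.2e-06, and adjusted p = 0.19 with an estimated correlation). The protease gene Ctss was at 60.2 ± 10.8 and 412 ± 88.0 FPKM.

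Of 18 genes of the Nrf2 response to oxidative stress 11 rose and 0 fell (15 and 0 adjusted over the list alone; median 1.28, adjusted p = 1.3e-08, and adjusted p = 0.11 with an estimated correlation). The haem oxygenase gene Hmox1 went from 182 ± 69.0 to 706 ± 134 FPKM. Of 32 cell cycle genes 20 rose and 0 fell (30 and 0 adjusted over the list alone; median 1.06, adjusted p = 1.2e-12, and adjusted p = 0.24 with an estimated correlation). Rrm2 was at 9.98 and 37.0 FPKM. Of 8 complement genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.98, adjusted p = 0.0017). C3 was at 4.90 ± 3.14 and 250 ± 235 FPKM. Of 23 cell death genes 7 rose and 0 fell (11 and 2 adjusted over the list alone; median 0.41, adjusted p = 9.8e-04), among them the inflammatory caspase gene Casp4 at 0.684 and 10.3 FPKM. With an estimated correlation the adjusted p was 0.11 for the complement and cell death lists. Mature astrocyte markers fell, 14 of 30 with 0 higher (16 and 1 adjusted over the list alone; median -0.84, adjusted p = 3.1e-07, and adjusted p = 0.17 with an estimated correlation). The transporter gene Slco1c1 was at 8.74 and 0.430 FPKM. Of 23 genes of cholesterol synthesis 10 fell and 0 rose (16 and 0 adjusted over the list alone; median -0.62, adjusted p = 3.8e-07, and adjusted p = 0.18 with an estimated correlation). Mvk was at 11.1 and 5.84 FPKM. Of 28 matrix genes 13 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.80, adjusted p = 5.9e-06, and adjusted p = 0.29 with an estimated correlation). Col4a1 was at 728 and 244 FPKM.

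Markers of other cell types shifted with the AD model too. Of 14 oligodendrocyte markers 11 rose and 0 fell (14 and 0 adjusted over the list alone; median 2.04, adjusted p = 7.3e-09, and adjusted p = 0.19 with an estimated correlation). Cldn11 was at 12.3 and 67.1 FPKM. Of 11 oligodendrocyte precursor markers 8 fell and 2 rose (8 and 3 adjusted over the list alone; median -0.94, adjusted p = 0.0026, and adjusted p = 0.18 with an estimated correlation). The transcription factor gene Olig1 was at 115 and 21.2 FPKM. Of 10 pericyte and smooth muscle markers 7 fell and 0 rose (9 and 0 adjusted over the list alone; median -2.42, adjusted p = 7.3e-07, and adjusted p = 0.17 with an estimated correlation). The growth factor receptor gene Pdgfrb was at 79.0 and 21.3 FPKM. Of 11 fibroblast markers 6 fell and 0 rose (9 and 0 adjusted over the list alone; median -1.27, adjusted p = 0.0012). Col1a2 was at 360 and 110 FPKM. That list was no longer called without AD model replicate 2 (adjusted p = 0.052) or with an estimated correlation (adjusted p = 0.34). Of 18 glycolysis genes 3 rose and 2 fell, also adjusted over the list alone (median 0.42, adjusted p = 0.028), a call lost without AD control replicate 2 (adjusted p = 0.11), without AD model replicate 2 (0.10) and with an estimated correlation (adjusted p = 0.47). Of 36 genes of oxidative phosphorylation 0 passed singly (median -0.15, adjusted p = 0.030). The call of that list was lost without AD control replicate 1 (median -0.009) and without AD model replicate 1 (median -0.12). It was also lost with the 4 libraries alone (adjusted p = 0.060) and with an estimated correlation (adjusted p = 0.65). Of 16 endothelial markers 1 rose, Ly6a, also adjusted over the list alone (median 0.81, adjusted p = 0.041). Without AD control replicate 2 the endothelial median was 0.15 (adjusted p = 0.64) and without AD model replicate 1 it was -0.11 (0.71). It was 1.47 without AD control replicate 1 and 1.86 without AD model replicate 2, and the adjusted p was 0.65 with an estimated correlation.

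In total 1373 genes were higher and 1019 lower in the AD model (17.1% of those tested, 57.4% of the calls higher), of which 852 and 402 differed by at least 1 on the log2 scale. The majority of higher genes was not kept with quantile normalization (49.3% higher) or the trend on GC content and length removed (49.9%), and was 50.3% without AD control replicate 2. A fit of the 4 AD libraries alone, which changes both the spread used and the residual degrees of freedom (2), called 278 genes, 86.0% of them higher. The same setting raised the calls from 5934 to 8704 in the cKO and from 5025 to 5814 with Aβ, so fewer degrees of freedom alone do not explain the loss in AD. AD replicates differed more, by a median of 0.287 (control) and 0.293 (AD model) on the log2 scale, against 0.104 to 0.164 in the other groups. The spread shared by all 12 libraries is thus small for AD, and the adjusted p of single genes in AD may be too small.

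The Aβ comparison asks what amyloid-beta does to cultured adult astrocytes. Cxcl1 and Mmp13 were among the 8 genes with the largest rise, and Actg2 and Igfbp6 among the 8 with the largest fall. Cxcl1 went from 0.407 ± 0.228 FPKM in the control to 249 ± 8.57 with Aβ (SD, n = 2; log2 change 7.48 ± 0.23, adjusted p = 5.9e-07), and Cxcl5 (chr5:90759360-90761624) was listed at 0 in both control libraries and at 125 ± 28.0 FPKM with Aβ. The collagenase gene Mmp13 (chr9:7272514-7283331) went from 3.14 ± 1.12 to 307 ± 17.0 FPKM (6.24 ± 0.82, adjusted p = 6.9e-04), H2-Q6 from 0.772 to 126, Irf7 from 1.73 to 114, the antiviral gene Ifit1 from 0.702 to 75.8, Fpr1 from 0.374 to 74.9 and Marco from 0.425 to 66.4. The smooth muscle actin gene Actg2 (chr6:83512905-83536265) fell from 559 ± 16.8 to 20.2 ± 4.12 FPKM (-4.74 ± 0.98, adjusted p = 0.0062). Mgp fell from 451 to 24.9 FPKM, Igfbp6 from 194 to 10.9, Nkain4 from 66.7 to 2.30, the glutamate transporter gene Slc1a6 from 64.9 to 4.95, the retinoic acid synthesis gene Aldh1a2 from 31.9 to 1.68, Elobl from 27.8 to 0.0354 and Eln from 17.8 to 0.314. Eln, with a log2 change of -3.83, lost its call without Aβ control replicate 1 (-3.92, adjusted p = 0.056), Aβ-treated replicate 1 (-3.89, 0.053) or Aβ-treated replicate 2 (-3.78, 0.052). Ogt was at 9.12 ± 1.80 and 11.5 ± 1.27 FPKM (0.32 ± 0.30, adjusted p = 0.44) and Mgea5 at 14.4 ± 2.98 and 20.5 ± 1.57 (0.49 ± 0.38, adjusted p = 0.33), so neither passed the test.

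Interferon-stimulated genes rose with Aβ, 30 of 31 with 0 lower, also adjusted over the list alone (median 4.29, adjusted p = 2.3e-23). Ifit3b went from 1.06 ± 0.619 to 61.3 ± 7.07 FPKM, Ifi44 from 0.105 to 22.1 and the RNA sensor gene Ifih1 from 0.296 to 12.7. All 16 genes of MHC class I presentation rose, also adjusted over the list alone (median 2.75, adjusted p = 1.3e-13). H2-Q4 was at 4.84 and 111 FPKM. Of 34 NF-kB genes 24 rose and 1 fell (27 and 1 adjusted over the list alone; median 2.09, adjusted p = 2.4e-12). Cxcl2 was at 1.00 and 54.8 FPKM and Ccl2 at 21.1 and 643. Of 11 A1 genes 7 rose and 1 fell (7 and 2 adjusted over the list alone; median 2.69, adjusted p = 0.0013), among them the granule proteoglycan gene Srgn at 9.87 and 69.2 FPKM. Of 23 cell death genes 13 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.80, adjusted p = 1.7e-04). Casp4 was at 0.196 and 10.1 FPKM. Genes of cholesterol synthesis fell, 20 of 23 with 0 higher, also adjusted over the list alone (median -1.16, adjusted p = 1.4e-10). Cyp51 was at 34.8 ± 2.45 and 6.21 ± 2.01 FPKM and Mvk at 21.2 and 6.24. With an estimated correlation the adjusted p was 0.14 for these 6 lists. In the same libraries 9 of 19 microglia markers rose and 2 fell (11 and 2 adjusted over the list alone; median 0.78, adjusted p = 0.0065, and adjusted p = 0.56 with an estimated correlation). Ctss was at 134 and 431 FPKM. Of 13 markers of disease-associated microglia 8 rose and 1 fell, also adjusted over the list alone (median 1.67, adjusted p = 0.010, and adjusted p = 0.14 with an estimated correlation). Clec7a was at 6.22 and 145 FPKM.

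Of 18 genes of the Nrf2 response 10 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.87, adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation). The glutathione reductase gene Gsr was at 14.7 and 44.4 FPKM. Of 8 complement genes 5 rose and 0 fell, also adjusted over the list alone (median 1.49, adjusted p = 0.0069, and adjusted p = 0.16 with an estimated correlation). C3 was at 4.22 and 57.0 FPKM. Of 36 genes of oxidative phosphorylation 13 fell and 0 rose, also adjusted over the list alone (median -0.31, adjusted p = 2.0e-05, and adjusted p = 0.56 with an estimated correlation). Ndufa4 was at 93.4 and 50.1 FPKM. Of 13 mitochondrially encoded transcripts 7 rose and 1 fell, also adjusted over the list alone, but that list was not called (median 0.50, adjusted p = 0.096). It was called with quantile normalization (0.44, adjusted p = 0.015) and without Aβ-treated replicate 2 (0.60, adjusted p = 0.035), and its median was 0.31 without Aβ-treated replicate 1 and -0.01 with the trend on GC content and length removed. Other cell types' markers also shifted. Of 14 oligodendrocyte markers 13 rose and 0 fell (14 and 0 adjusted over the list alone; median 2.27, adjusted p = 2.7e-07, and adjusted p = 0.37 with an estimated correlation). Cldn11 was at 1.45 and 32.6 FPKM. Of 16 endothelial markers 12 rose and 0 fell (13 and 0 adjusted over the list alone; median 2.29, adjusted p = 1.6e-04, and adjusted p = 0.56 with an estimated correlation). Pecam1 was at 18.1 and 142 FPKM. Of 10 pericyte and smooth muscle markers 7 fell and 0 rose, also adjusted over the list alone (median -2.36, adjusted p = 0.0014, and adjusted p = 0.42 with an estimated correlation). Acta2 was at 3346 ± 288 and 382 ± 43.8 FPKM. Of 11 fibroblast markers 6 fell and 1 rose, also adjusted over the list alone (median -1.53, adjusted p = 0.033), a call lost without Aβ control replicate 1 (adjusted p = 0.056), with quantile normalization (0.078) and with an estimated correlation (adjusted p = 0.60). The mature astrocyte markers were not called (4 of 30 rose and 4 fell, median -0.06, adjusted p = 0.78).

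In total 2915 genes were higher and 2110 lower with Aβ (35.9% of those tested, 58.0% of the calls higher), and 2171 of these differed by at least 1 on the log2 scale. The effect followed the GC content of the transcripts, with r = -0.28 across 14003 genes (genes are not independent replicates). In the decile of genes with the lowest GC content 49.8% were called higher and 2.43% lower, and in the highest decile 9.21% and 27.2%. With the trend on GC content and gene length removed per library, a setting chosen after seeing the data, 4666 genes were called, 44.8% of them higher, and 3620 of the 5025 kept their call and direction, while all 15 called lists stayed called. Without Aβ control replicate 1 the count was 2674, without Aβ-treated replicate 1 it was 2830 and without Aβ-treated replicate 2 it was 3305.

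**Figure D3:**
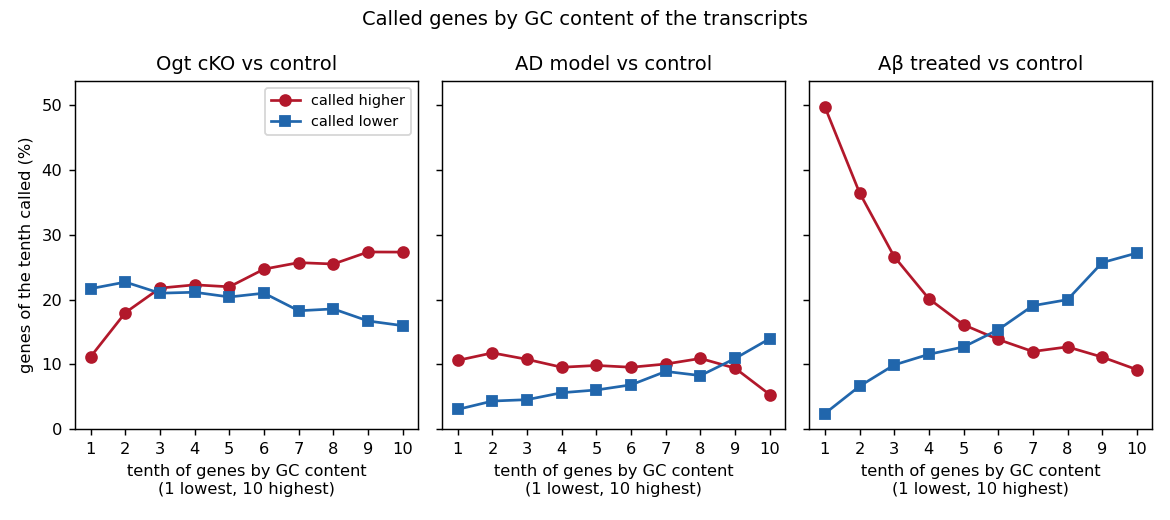
Percent of genes called higher (circles) and lower (squares) on the vertical axis in each decile of genes by GC content of their transcripts (1 lowest, 10 highest) on the horizontal axis, 1 panel per comparison. In the Aβ panel the share called higher goes from 49.8% in the lowest decile to 9.21% in the highest, against 10.6% and 5.35% in the AD panel and 11.2% and 27.3% in the Ogt cKO panel.

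The series sets the loss of Ogt beside the amyloid model and exposure to the peptide, and the 3 effects share no control library. The AD and Aβ effects ran in parallel, with r = 0.69 across the 14014 genes (Spearman's rho 0.52), described only since genes are not independent replicates. They shared 989 genes higher in both (286 by chance) and 568 lower in both (153 by chance). The exact one-sided hypergeometric test, which treats genes as independent, gave p = 2.5e-221 for those lower in both. The difference of the effects itself passed for 861 genes (6.14%). That last number was 540 with no filter on low values, 531 with a filter at 5 FPKM and 492 with the GC and length trend removed. Markers of several cell types shifted the same way in AD and Aβ. Their medians were 2.04 and 2.27 for oligodendrocytes and -2.42 and -2.36 for pericytes and smooth muscle. Those of fibroblasts were -1.27 and -1.53 and those of microglia 1.28 and 0.78. Oligodendrocyte precursor markers did not run alike (-0.94 and 0.66). Whether altered shares of cells make up part of the parallel was not tested. The cKO and AD effects had r = 0.10, with 388 genes higher in both (310 by chance) and 300 lower in both (201 by chance), and differed for 3593 genes. The cKO and Aβ effects ran opposite, with r = -0.23. The Ogt cKO libraries correlated with the Aβ control libraries at r = 0.975 to 0.981, and with their own control at 0.871 to 0.894. The opposite signs may therefore reflect this likeness rather than opposed effects of Ogt loss and Aβ, which was not tested. The difference between the Aβ control and AD control libraries correlated across genes with the cKO effect at r = 0.66 and with the Aβ effect, which holds the same Aβ control libraries, at -0.41. The cKO and Aβ effects shared 242 genes higher in both (658 by chance) and 137 lower in both (417 by chance). Another 941 genes were higher in the cKO and lower with Aβ (477 by chance), and 932 the reverse (576 by chance). Their effects differed for 7327 genes (52.3%).

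**Figure D4:**
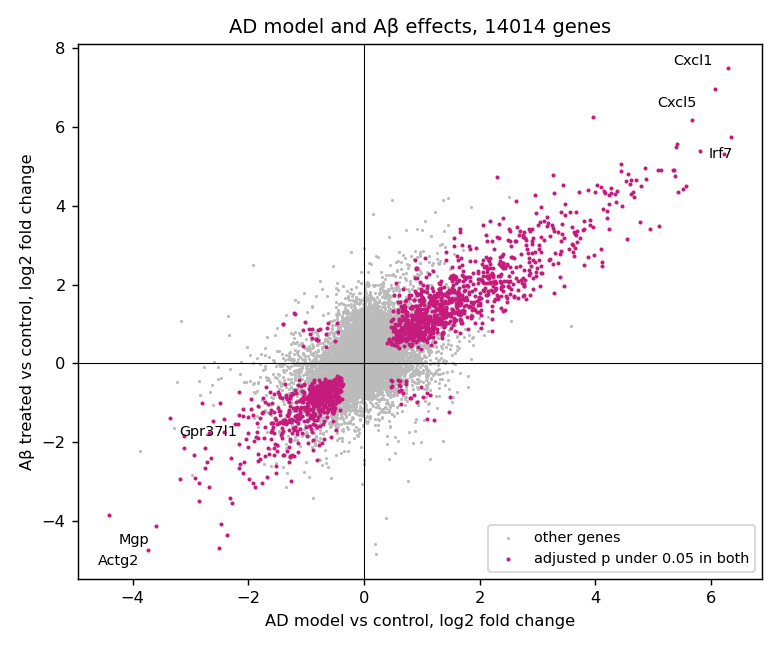
Log2 fold change of each of 14014 genes in the AD model against its control (horizontal axis) and with Aβ against its control (vertical axis), with genes called in both comparisons in magenta and the others in grey. The effects correlate at r = 0.69, and 989 genes are called higher and 568 lower in both.

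Of the 989 genes higher in both AD and Aβ, 169 were higher in the cKO as well (223 by chance) and 243 lower in it (195 by chance). Of the 568 lower in both, 86 were lower in the cKO as well (112 by chance) and 166 higher in it (128 by chance). The genes higher in all 3 comparisons held the chemokine genes Cxcl1 (log2 change 3.92 in the cKO, 6.30 in AD and 7.48 with Aβ), Cxcl2 (5.26, 4.56 and 4.80), Cxcl5 (1.84 and 6.07, and listed at 0 in the Aβ control), Ccl2 (6.01, 5.35 and 4.91) and Ccl7 (5.94, 4.78 and 3.60), and Marco, Fpr1 and Acod1. The interferon list separated the effects, with a median difference of -3.80 between the cKO and AD effects (adjusted p = 5.0e-23) and of -3.76 between the cKO and Aβ effects (adjusted p = 1.8e-13), and so did MHC class I (-2.93, adjusted p = 3.7e-15, and -2.94, adjusted p = 5.1e-09). With an estimated correlation these differences had adjusted p = 0.22 and 0.37 for interferon and 0.18 and 0.37 for MHC class I. The NF-kB list as a whole did not differ by the test between cKO and AD (adjusted p = 0.96), cKO and Aβ (0.37) or AD and Aβ (0.33). Single members did differ, in both directions. Of its 34 genes 5 were higher and 5 lower in the cKO effect than in the AD effect. Against the Aβ effect 11 were higher and 6 lower in the cKO effect, and between AD and Aβ 0 differed either way. The cell cycle genes were higher in the AD effect than in the Aβ effect (median difference 1.28, adjusted p = 5.1e-10, and adjusted p = 0.90 with an estimated correlation), and the mature astrocyte markers lower (-0.95, adjusted p = 2.1e-05, and adjusted p = 0.69 with an estimated correlation).

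**Figure D5:**
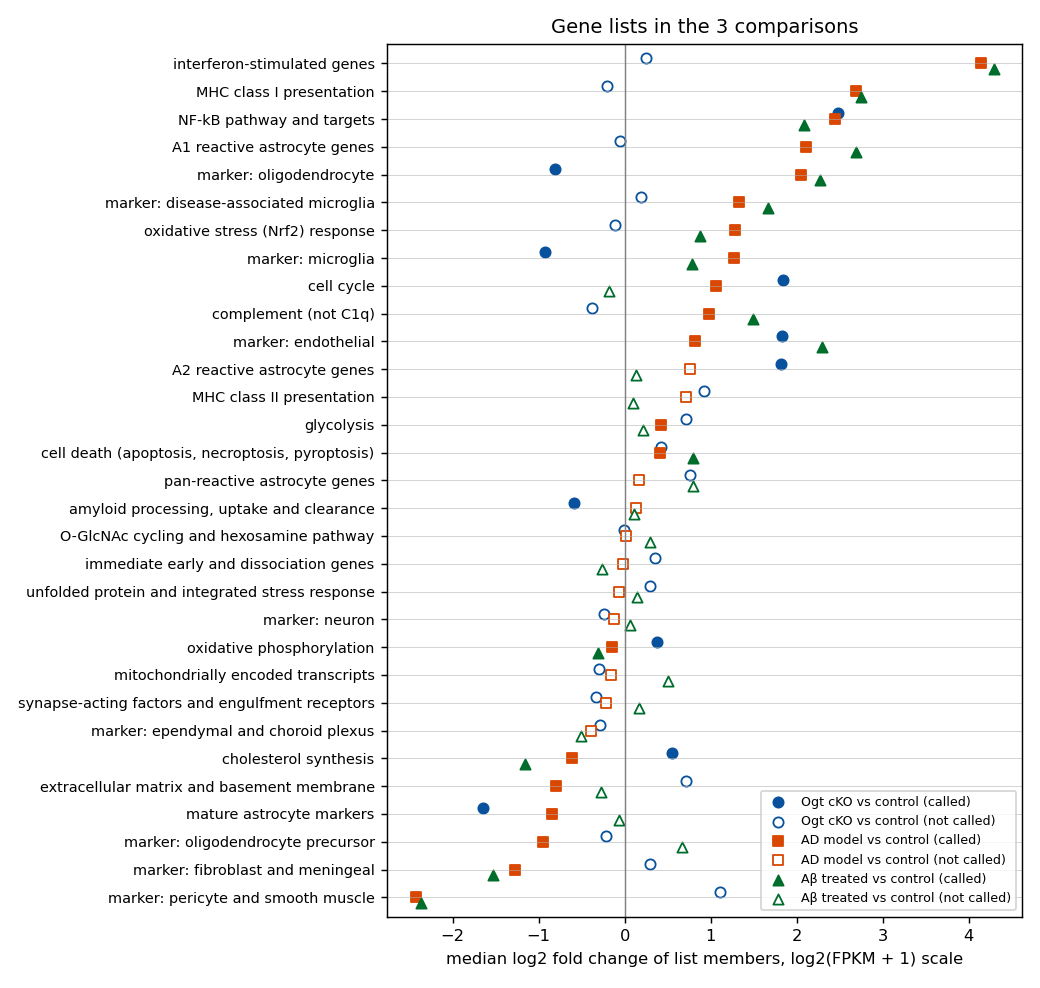
Median log2 fold change over the members of each of 31 gene lists (horizontal axis, log2(FPKM + 1) scale), with circles for the Ogt cKO, squares for the AD model and triangles for Aβ, each against its control, filled where camera called the list. The interferon list lies at 4.15 and 4.29 in AD and Aβ and at 0.25, not called, in the cKO, and the NF-kB list at 2.48, 2.44 and 2.09.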

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

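The differences between effects had been planned, and the tests of explanations were chosen only after the results were seen. Differences between the effects of the experiments stood out in the contrasts of the fit. The effect differed for 3593 genes and 13 lists between cKO and AD, for 7327 genes and 13 lists between cKO and Aβ, and for 861 genes and 7 lists between AD and Aβ. Each of these lists lost its call with an estimated correlation, the lowest adjusted p being 0.18, 0.37 and 0.65.

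The largest differences between the cKO and AD effects were those of the smooth muscle actin gene Actg2 (8.21 on the log2 scale), Crct1 (7.55), Eln (7.34) and Msln (6.88), all higher in the cKO effect. Between cKO and Aβ they were those of Gm10036 (10.05), Msln (9.41), Actg2 (9.21) and Crct1 (8.77). Between AD and Aβ they were those of Gm8730 (5.05), Gm10036 (4.78), Gm12191 (-4.43) and Nov (-4.23). Gm10036 was at 172 ± 72.5 FPKM in the Ogt cKO, 159 ± 65.8 in the Aβ control and 2.76 to 5.48 in the other groups, and Gm8730 at 302 ± 363 in the Aβ control, so its replicates differ by more than their mean. These 3 genes carry names given to predicted genes, and whether their reads belong to near-identical copies was not tested.

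Many of the genes changed in the Ogt cKO also differ between control libraries. Across genes the cKO effect correlated at r = 0.679 with AD control replicate 1 minus AD control replicate 2. That is a difference between wild-type libraries of 1 group, and the Aβ effect gave -0.117 with it. It had the same sign for 90.1% of the genes called higher in the cKO and 84.7% of those called lower. The AD effect gave 0.003, but it holds the mean of both of these control libraries, so that value is no independent comparison. The cKO effect also correlated at r = 0.464 with AD model replicate 1 minus AD model replicate 2, where the Aβ effect gave -0.036. The replicate differences of the AD control and the AD model themselves correlated at 0.551, so they are not independent comparisons. A state of the cultures, such as density or passage, that also varies between control libraries may therefore make up part of the cKO effect. Ogt itself was at 10.0 and 22.7 FPKM in the AD control libraries. GC content or gene length bias as the cause of the resemblance was not tested, since the correlation was not recomputed with that trend removed. The AD control libraries differed in their slope on GC content (-0.0447 and -0.156 log2 units per 10 percentage points). As the whole cause of the cKO calls such bias is argued against. With the trend removed, 79.4% of the called genes kept their call and direction. A lower share of astrocytes with all other cell types rising alike is argued against too. The endothelial markers lay 2.75 above the microglia markers in median log2 change (SD over members 1.49 and 1.30). A lower share with unequal shifts of the other cells is not excluded by that. Astrocyte (median -1.64), microglia (-0.92) and oligodendrocyte markers (-0.81) fell and endothelial markers rose (1.83), so it stays open. Loss of Ogt remains open as a cause, because the tests do not separate it from such a state of the cultures. So does a mix-up of a control library, which was not tested on its own. AD control replicate 2 lay closer to cKO control replicate 1, at r = 0.963, than to its own replicate, at 0.948. The difference between the AD model replicates holds no control library, so a mix-up of a control library would not by itself produce that difference.

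Inflammatory genes and microglia markers moved together in AD and Aβ but apart in the cKO. More microglia could raise both, yet in the cKO the microglia markers had a median of -0.92 while the NF-kB genes rose. The interferon list lay above the microglia markers by 2.87 in AD and 3.51 with Aβ (larger SD over members 1.38 and 1.29). These values argue against the number of microglia alone. Changed numbers of other cells, macrophages and other immune cells among them, were not tested as a cause and stay open. In the cKO endothelial markers rose (median 1.83). So did the scavenger receptor gene Marco (0.309 and 71.5 FPKM), Fpr1 (log2 change 3.76) and Acod1 (5.02), against the fall of the microglia markers. The NF-kB list lay only 1.17 and 1.31 above the microglia markers in AD and Aβ, within its SD over members (1.77 and 1.92). For that list in AD and Aβ more microglia and a response of the astrocytes cannot be told apart. Microglia that are more active without being more numerous, and a response of the astrocytes, both stay open, with no sort described that would remove microglia and with their gene Ctss at 412 FPKM in the AD model and 431 with Aβ.

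The Aβ effect followed the GC content of transcripts, with the slope of expression on it differing by -0.408 log2 units per 10 percentage points (treated minus control libraries). GC content or length bias as the whole cause of the calls is argued against, since 72.0% of the called genes kept their call and direction with the trend removed. As the cause of the trend itself it cannot be told apart from the treatment, because the larger gap between replicates of 1 group (0.160, in the control) was 0.392 of the difference between the groups, and the labels do not say whether control and treated libraries were prepared together. A broad effect of Aβ on GC-poor transcripts stays open as well.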

How the results depend on the processing

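Voom on recovered reads, rescaling to the total of recovered reads, the removal of the GC and length trend and the crossed pairing were chosen after seeing the data. Over all alternatives 6833 values of named genes kept their direction and side of the threshold, 394 became weaker, 72 stronger and 1 reversed, and of lists 1023, 55, 37 and 1. The reversed ones were Kdm5d with Aβ (-0.0592 with the GC and length trend removed, 0.57 without) and the endothelial list in AD (-0.11 without AD model replicate 1 to 1.86 without AD model replicate 2). The Ogt change in the cKO was -0.92 with no filter (adjusted p = 0.088, over more genes), -0.74 with the GC and length trend removed (0.062) and -1.03 to -0.80 with 1 library left out. With 1 library fewer the genes called were 1857 to 3213 in the cKO (5934 with all) and 2674 to 4033 with Aβ (5025 with all); the lone sample of a group is then assumed to vary like the other groups. In AD they were 2173 to 2421, but 278 (86.0% higher) with the 4 AD libraries alone, a setting that called 8704 in the cKO and 5814 with Aβ.

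A minimum log2 change of 1 left 2310 genes in the cKO, 1254 in AD (67.9% higher) and 2171 with Aβ (72.9% higher), by construction. The genes whose effect differs between AD and Aβ were 540 with no filter, 531 at 5 FPKM and 492 with the trend removed (861 before). With an estimated correlation 0 lists were called up and 0 down in the cKO (6 and 4 before), 5 and 0 in AD (13 and 7) and 0 and 0 with Aβ (11 and 4), while fry called 9 and 4, 13 and 6, and 14 and 5. The share of calls that were higher was 35.5% in the cKO with rescaling to totals (53.3% before), and with Aβ 47.4% with quantile normalization and 44.8% with the trend removed (58.0% before). Where no construction is named the cause was not tested.

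With the replicate number as a block 6789 genes were called in the cKO, 3058 in AD and 6098 with Aβ, and the shared genes were 472 lower in cKO and AD (300 before), 417 higher in cKO and Aβ (242) and 307 lower in both of these (137). Mgea5 with Aβ (0.49) passed in that fit (adjusted p = 0.041). No label says that a number marks a shared animal, batch or day. The deviations of same-numbered replicates correlated at 0.033 in the cKO, 0.551 in AD, where they went together, and -0.169 with Aβ, where a crossed pairing called 4803. Median-of-ratios scaling, a near-constant factor since the deposited values were on that scale, called 5935, 2395 and 5022 genes and says nothing about stability. Depth limits genes under about 0.145 to 0.191 FPKM at 1 kilobase, equal to 3 reads.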

Other observations

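The hexosamine pathway, which makes the sugar donor used by Ogt, split in the Ogt cKO. Uap1 was at 10.6 ± 0.598 FPKM in the control and 17.8 ± 0.597 in the cKO, Pgm3 at 5.06 and 9.40 and Gfpt2 at 1.55 and 5.50, all 3 higher, and Gnpda1, whose product works against this pathway, was lower (32.7 FPKM in the control, log2 change -1.38). With Aβ Gfpt2 was higher too (3.74 and 8.86 FPKM), but Pgm3 (8.86 and 4.43) and Uap1 (14.1 and 10.8) were lower. The list as a whole was not called in the cKO (3 of 13 rose and 4 fell, median -0.01, adjusted p = 0.91), AD (1 rose, median 0.02, adjusted p = 0.80) or Aβ (1 rose and 2 fell, median 0.30, adjusted p = 0.57). The growth factor gene Bdnf, which acts on neurons, rose in the cKO from 1.83 ± 0.918 to 9.37 ± 1.03 FPKM but fell in AD from 8.84 to 2.75 and with Aβ from 10.6 to 2.56. The engulfment receptor gene Mertk fell in the cKO from 14.9 to 5.76 FPKM and rose in AD from 4.80 to 17.8 and with Aβ from 6.23 to 39.7.

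Lactate dehydrogenase Ldha was higher in the cKO (181 ± 32.4 and 482 ± 24.2 FPKM), as was the secreted Spp1 (369 and 3560), while its fellow marker of disease-associated microglia Trem2 was lower (65.6 and 5.36). The protease inhibitor gene Timp1 was at 149 and 2955 FPKM. Lcn2, a secreted marker of reactive astrocytes, was higher in all comparisons, at 2.75 and 22.2 FPKM in the cKO, 13.5 and 397 ± 195 in AD and 14.8 and 392 with Aβ. The pan-reactive list it belongs to was not called (adjusted p = 0.21, 0.058 and 0.11 for cKO, AD and Aβ), but was without AD control replicate 1 (0.012), AD model replicate 1 (0.044) or Aβ-treated replicate 2 (0.039), with quantile normalization (AD and Aβ both 0.030) and with the GC and length trend removed (AD 0.043, Aβ 0.038). Of the 31 lists, 21 were not called in the cKO (adjusted p from 0.13 to 0.91), 11 in AD (0.058 to 0.93) and 16 with Aβ (0.068 to 0.97). The glycolysis list with Aβ (median 0.21) was called with quantile normalization (median 0.44, adjusted p = 0.0013) or the GC and length trend removed (median 0.31, adjusted p = 0.022). It was also called without Aβ control replicate 1 (median 0.35) or Aβ-treated replicate 1 (median 0.38). The A2 list in AD (median 0.76) was called with quantile normalization (median 0.75, adjusted p = 0.037). It was also called without AD control replicate 1 (median 1.15) or AD model replicate 2 (median 1.46). Other lists passed under single settings. In the cKO these were the glycolysis list (0.040) and matrix list (0.041) with the trend removed, the matrix list with the replicate block (0.041), the mitochondrially encoded transcripts with quantile normalization (0.038) and the immediate early genes without cKO control replicate 2 (0.033). In AD they were the mitochondrially encoded transcripts with the trend removed (0.0024) and the unfolded protein list without AD control replicate 2 (0.032), and with Aβ the matrix list without Aβ-treated replicate 2 (0.035). In some of the lists not called, median and mean had opposite signs, for example the neuron markers in the cKO (median -0.25, mean 0.48). The blood cell list had 1 measured gene, S100a8, at 0.146 and 4.55 FPKM in the cKO, 0.0436 and 3.37 in AD and 1.35 and 10.5 with Aβ.

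The Y-linked Ddx3y was at 2.07 ± 0.0319 FPKM in the Aβ control and 8.82 ± 1.35 with Aβ (log2 change 1.67, adjusted p = 6.4e-05), and at 0.99 (adjusted p = 7.4e-04) with the GC and length trend removed. Uty, Kdm5d and Eif2s3y were higher by 0.88, 0.57 and 0.82, but none of the 3 passed with that trend removed (0.10, -0.06 and 0.14, adjusted p = 0.61, 0.74 and 0.60). The X-linked Ddx3x rose too (1.40, adjusted p = 0.0032, and 0.80, adjusted p = 0.023, with the trend removed), as did Kdm6a (0.91, adjusted p = 0.0055), which did not pass with the trend removed (0.41, adjusted p = 0.088).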
